A study of Homo sapiens with 6 samples.

How the data were processed

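Gene expression was measured in HCT116, an established human colon cancer cell line, on Affymetrix Human Genome U133 Plus 2.0 arrays. On this platform each transcript is read by sets of short probes, and each probe set gives 1 brightness value per array. Cells received either a non-targeting control siRNA or an siRNA against YAP1, at 100 nM for 36 h in medium with 2% serum, per the labels. Each group had 3 arrays, and the series' design text calls them independent biological replicates that were transfected in parallel. Per the labels' protocols, RNA was extracted with Trizol and biotinylated cRNA was prepared from 1 µg of total RNA.

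The deposited values were linear probe set intensities, 1 per probe set and array, already summarised from the probes. Per the submitters' processing notes, MAS5 (Affymetrix's algorithm for background adjustment and probe set summary) was used, with no version, scaling target or detection call named. The means of the arrays after trimming 2% of values at each end ran from 70.4 to 75.9, whereas MAS5 global scaling alone would have made them equal. How the arrays were scaled to each other is therefore unknown, and results that depend on it are given under other scalings too. No scanner files were used here.

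The table held 54675 probe sets, of which 62 were Affymetrix controls. A platform annotation table gave exactly 1 gene symbol for 41097 probe sets, several for 1801 and none for 11777. Symbols were checked against NCBI RefSeq gene names (GRCh38.p14) by Entrez identifier, which matched for 41043 probe sets and changed 0 symbols. Probe sets with several symbols or none were left out of the gene fit. No coordinates are given.

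Intensities were analysed as log2(intensity + 1) with the deposited scaling. Fold changes are on that scale, which understates the change of dim genes. Each gene was represented by the single-gene probe set with the highest mean over all 6 arrays, and genes were kept where that mean reached the median of all non-control probe sets, a log2 value of 4.19 or an intensity of 17.3. This left 12797 of 19775 genes. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend, two-sided), with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. Adjusted p-values of single genes below come from this fit, and errors beside log2 fold changes are its standard errors. Where single probe sets of a gene are compared, the same model was fitted over all non-control probe sets. Single values per array were compared by an exact permutation test, two-sided, whose smallest possible p with 3 arrays against 3 is 0.1.

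The 18 gene lists, the markers of other cell types, the rule for naming genes and the alternatives were fixed before the data were examined. The rule named YAP1, WWTR1 and the TEAD genes, the 10 largest rises and 10 largest falls among changed genes whose arrays did not overlap between groups, and up to 4 members of smallest p in each list. It also allowed any further list member needed to say what moved. The 16 members named under that last part were picked after their values were seen. The lists were tested with limma's camera at a preset inter-gene correlation of 0.01, which asks whether a list moved relative to the other genes, with adjustment over the 18 lists. Members are called measured where they were kept in the gene fit, which left out dim genes. Of 22 YAP/TEAD targets 17 were kept, of 26 intestinal differentiation genes 11 and of 18 mesenchymal genes 8. The lists were YAP/TEAD targets, Hippo pathway components, DNA replication, mitosis, ribosome biogenesis and MYC, Wnt/beta-catenin targets, p53 targets, interferon-stimulated genes, the integrated stress and unfolded protein response, cholesterol synthesis, glycolysis and hypoxia, MAPK output, actin cytoskeleton and SRF targets, epithelial junction and keratin genes, mesenchymal genes, intestinal differentiation, apoptosis regulators and housekeeping genes.

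The alternatives were quantile normalization, centring each array on its 75th percentile, a pseudocount of 32, no filter, a filter at the 70th percentile, eBayes without the trend or with robust settings, the mean of a gene's probe sets, leaving out probe sets whose identifiers end in _x_at (which may bind several transcripts), testing every probe set, the replicate number as a block, leaving out each array, camera with an estimated correlation, and fry, a test of whether a list's genes move one way on balance. The gene fit was tested on simulated data with the spread of the 12797 real genes and 200 changed genes. It recovered 100% of genes changed by a log2 of 1 in either direction, 92% of those raised by 0.5 and 86% of those lowered by 0.5. Of its 197 calls, 8 were false. The simulation drew independent noise for each gene, held no shift of whole arrays and had as many rises as falls. It therefore does not test calls that depend on scaling, nor changes smaller than a log2 of 0.5. The number of arrays limits the precision of all values.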

Results

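The data comprised 6 arrays of HCT116 colon cancer cells, 3 treated with a control siRNA and 3 with an siRNA against YAP1, a transcriptional coactivator that the Hippo kinase cascade restrains. The summed intensity per array ran from 7148825 to 7524779. Pearson's r across probe sets was 0.9948 to 0.9969 within groups and 0.9877 to 0.9931 between groups, so no array duplicated another and each array resembled its own group most. The comparison asked which transcripts differ between cells given the YAP1 siRNA and cells given the control siRNA. The labels do not give the siRNA sequence or say whether a pool was used. For every gene and list below, effects of the siRNA on other transcripts therefore cannot be told apart from effects of YAP1 loss.

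YAP1 itself, the siRNA's target, fell 2.76-fold on its brightest probe set, from an intensity of 470 ± 50.3 to 170 ± 15.5 (SD, n = 3), a log2 fold change of -1.46 ± 0.08 (limma adjusted p = 1.37e-07). In the fit over all probe sets, the other 2 YAP1 probe sets changed by -1.71 ± 0.06 and -1.62 ± 0.13, so that 30.5% to 36.2% of the control level was left across the 3 probe sets. WWTR1, which encodes the YAP1 paralog TAZ, had a log2 fold change of -0.17 ± 0.10 and did not pass the test (adjusted p = 0.25). None of the 4 TEAD genes, which encode the DNA-binding partners of YAP1, passed it either, with log2 fold changes of -0.13 for TEAD1 (adjusted p = 0.0669), 0.07 for TEAD2, 0.02 for TEAD3 and -0.13 for TEAD4. TEAD1 lay lower on all 3 YAP1 siRNA arrays than on any control array, at 523 ± 12.6 against 573 ± 13.7, and passed the threshold in 1 alternative, without control array 3 (adjusted p = 0.0443).

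**Figure D1:**
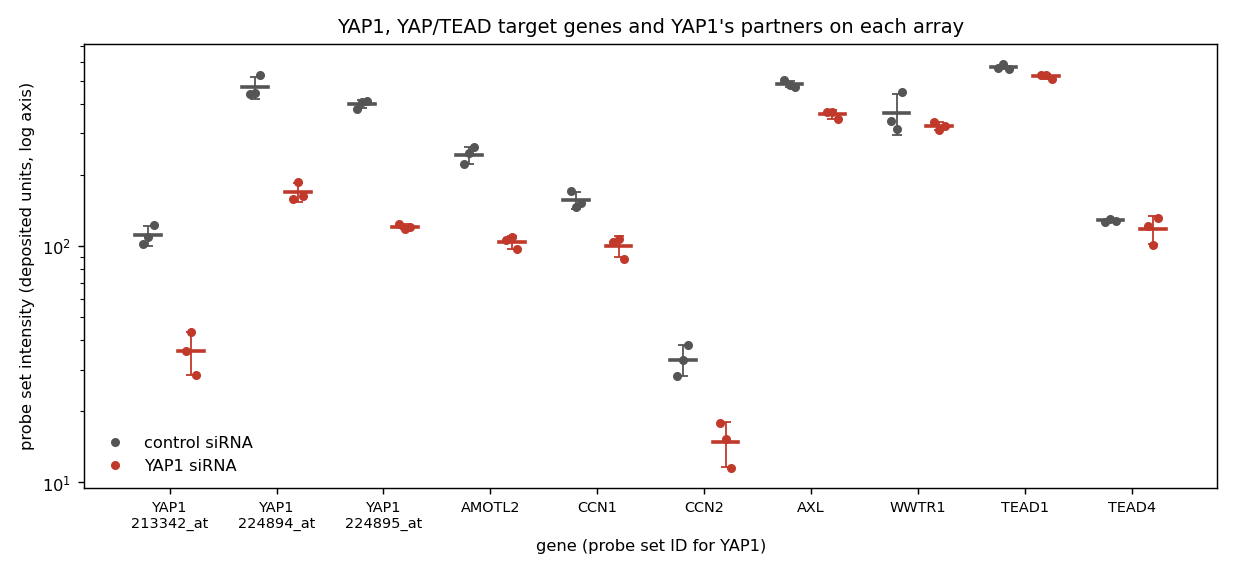
Intensity (log axis) of the 3 YAP1 probe sets, of 4 YAP/TEAD target genes and of WWTR1, TEAD1 and TEAD4 on each array, with points for arrays, thick lines for means and bars for the SD (n = 3). The YAP1 siRNA arrays lie below all control arrays for YAP1, AMOTL2, CCN1, CCN2, AXL and TEAD1, and TEAD1 has an adjusted p of 0.0669.

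With YAP1 siRNA, 2625 of 12797 genes changed, 543 higher and 2082 lower, so that 79.3% of changed genes were lower. This split depended on how the arrays were scaled: quantile normalization gave 997 higher and 1250 lower, and centring on the 75th percentile gave 1146 higher and 1164 lower. Of the 2082 lower genes, 1248 were also called lower after quantile normalization and 1164 after 75th percentile centring, and 0 genes were called in the opposite direction. The 75th percentile of intensity was itself lower on the YAP1 siRNA arrays, at 69.8 ± 1.86 against 73.6 ± 0.08 (exact permutation p = 0.1, the smallest possible). The shift was not the same over the range. The median intensity was 17.3, 17.4 and 17.6 on the YAP1 siRNA arrays against 17.2, 17.2 and 16.9 on the control arrays. The highest intensity was 13361 to 13468 against 12535 to 12876, but on each YAP1 siRNA array it was that of a single probe set, of ND4. Other bright genes were mixed. From control to YAP1 siRNA arrays, COX1 went from 11362 to 12223, EEF1A1 from 12604 to 12669 and GAPDH from 8621 to 8026. A shift that depends on intensity was not tested as a source of the split. Most changes were small, with a median of 1.24-fold. Only 10 genes changed at least 2-fold, 2 of them higher and 8 lower, and 168 changed at least 1.5-fold, 20 higher and 148 lower. At least 1.5-fold, 37 genes were higher and 87 lower after quantile normalization, and 50 higher and 86 lower after 75th percentile centring. With the deposited scaling, the arrays of both groups did not overlap for 37.6% of tested genes, against 10% by chance for a single gene. A shift shared by the genes of an array could raise this share, and it is not given for the other scalings.

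On the probe set that represented each gene, DHRS2, a short-chain dehydrogenase gene, fell furthest, from 478 ± 20.7 to 160 ± 17.1, a log2 fold change of -1.58 ± 0.08. Its other probe set was at -0.85 ± 0.08, and with the mean of probe sets DHRS2 (-1.21) fell less than YAP1 (-1.60). AMOTL2, an angiomotin family member that binds YAP1, fell 2.32-fold, from 244 ± 20.2 to 104 ± 6.62. SLC7A1, a cationic amino acid transporter, fell 2.22-fold from a high level of 2055 ± 32.9 to 926 ± 27.1. The chemokine gene CCL20 fell from 942 ± 29.7 to 429 ± 31.6, and the collagen gene COL12A1 from 110 ± 4.37 to 50.4 ± 5.06. CCN2, the gene of connective tissue growth factor, fell from 33.1 ± 4.98 to 14.9 ± 3.22, which ended below the intensity filter. UBA1, the main ubiquitin-activating enzyme, fell by 1.02 on the log2 scale, and JCAD and FAM111A each fell by 0.99.

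The largest rise was that of AQP3, a water and glycerol channel, from 504 ± 30.2 to 1067 ± 48.7, a log2 fold change of 1.08 ± 0.05, and all 3 of its probe sets were higher. MMP1, an interstitial collagenase, rose 2.07-fold from a level close to the filter, 17.8 ± 3.32 to 37.7 ± 6.17. PRDM1, a transcriptional repressor, was as dim, at 16.0 ± 2.13 and 29.1 ± 4.06 (log2 fold change 0.82 ± 0.13), and its other probe set above the filter had a log2 fold change of 0.35 with an adjusted p of 0.178. The Wnt ligand gene WNT16 rose by 0.75 ± 0.13 on a probe set that may bind several transcripts, and its other probe set had a log2 fold change of 0.35 with an adjusted p of 0.101. G3BP2, a stress granule protein gene, rose by 0.66 ± 0.08 on 1 probe set, while 2 others above the filter had log2 fold changes of 0.03 and 0.06. FAM3C, which encodes a secreted protein, rose from 979 ± 184 to 1481 ± 28.8. LINC01003 (0.92), ERICH1-AS1 (0.70), NDUFV1-DT (0.64) and CARNMT1 (0.64) made up the rest of the 10 largest rises among changed genes whose arrays did not overlap between groups. The calls of these 10 rises and of the 10 largest falls were kept in every alternative in which the gene was tested, but their sizes moved. With the mean of probe sets the log2 fold change was -0.73 for SLC7A1, -0.62 for FAM111A, -0.56 for UBA1, 0.35 for CARNMT1, 0.34 for FAM3C, 0.27 for ERICH1-AS1 and 0.25 for G3BP2. This mean takes in probe sets below the filter. For FAM111A, UBA1, CARNMT1, FAM3C and ERICH1-AS1 every other probe set lay there, at control means of 5.22 to 11.6. Dim probe sets thus pulled the values of these genes toward no change. With a pseudocount of 32, which damps dim genes, it was -0.47 for CCN2, -0.43 for JCAD, 0.48 for MMP1, 0.44 for LINC01003, 0.37 for NDUFV1-DT and 0.35 for PRDM1 and ERICH1-AS1, and without _x_at probe sets it was 0.35 for WNT16.

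**Figure D2:**
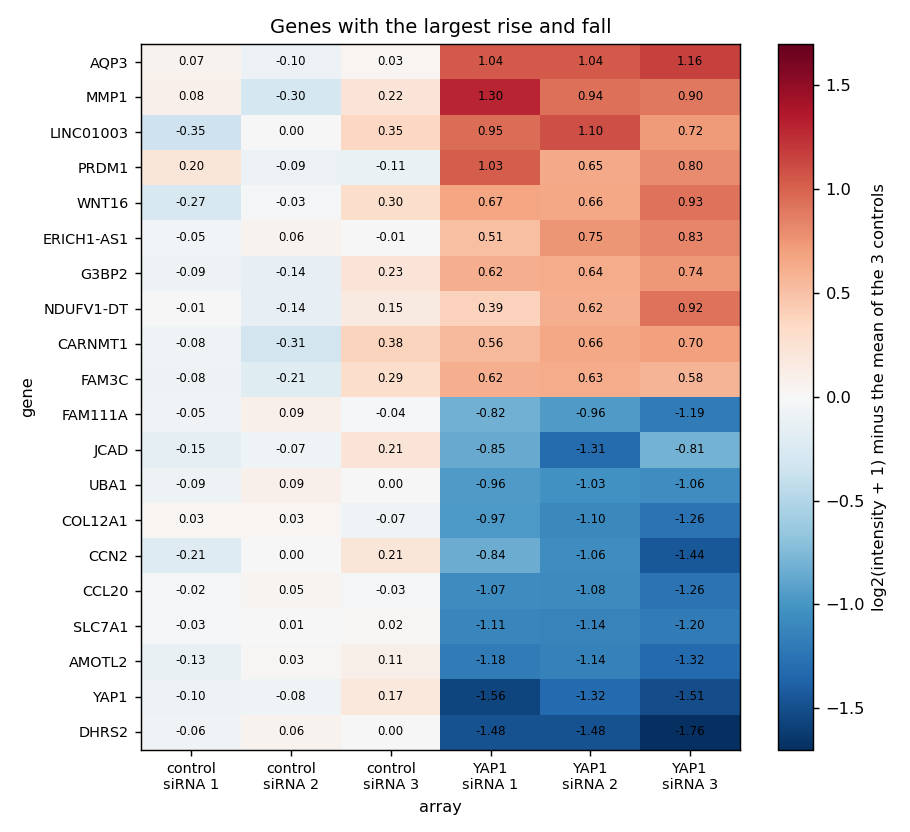
Log2(intensity + 1) of the 10 genes with the largest rise and the 10 with the largest fall among changed genes whose arrays did not overlap between groups, minus the mean of the 3 control arrays, for each of the 6 arrays (colour and printed value). DHRS2 has the lowest mean (-1.58) and AQP3 the highest (1.08).

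Among 17 measured YAP/TEAD targets, genes known to be driven by YAP1 with TEAD factors, 9 fell, 0 rose and 8 did not pass the test, and adjusted over the list alone 9 fell. Besides AMOTL2 and CCN2, the members that fell included CCN1, a matricellular protein gene (-0.65 ± 0.09, 157 ± 12.6 to 99.8 ± 10.1), GADD45B (-0.48 ± 0.08) and the receptor tyrosine kinase gene AXL (-0.42 ± 0.05). F3, the tissue factor gene, was at 142 ± 8.71 and 140 ± 6.27. The list's median log2 fold change was -0.19, and it was lower relative to other genes (limma camera adjusted p = 9.48e-04). That call was lost with an estimated inter-gene correlation (adjusted p = 0.381). With the mean of a gene's probe sets, AXL no longer passed (-0.20, adjusted p = 0.0855).

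Of 26 measured Hippo pathway components, 9 fell and 1 rose, and adjusted over the list alone 13 fell and 2 rose. AMOTL2, PTPN14 and LATS2 are among these 9 falls and also among the YAP/TEAD targets that fell, so the lists are not separate. Apart from AMOTL2, the falls were led by the FERM-domain gene FRMD6 (-0.86 ± 0.08, 168 ± 9.55 to 92.5 ± 4.47), AJUBA (-0.59 ± 0.07), an inhibitor of LATS kinases, and MOB1A (-0.37 ± 0.06), an activator of them. The gene that rose was the atypical cadherin FAT1 (0.18 ± 0.04). The list as a whole missed the threshold (camera adjusted p = 0.0533, and adjusted p = 0.484 with an estimated correlation), though it passed in some alternatives, such as 75th percentile centring (adjusted p = 0.0206).

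Of 38 mitosis genes, 35 fell, 1 rose and 2 did not pass, and adjusted over the list alone 36 fell and 1 rose. The median log2 fold change was -0.66 (camera adjusted p = 1.18e-25), a call lost with an estimated correlation (adjusted p = 0.226). CDC20, an activator of the anaphase-promoting complex, fell from 780 ± 49.3 to 393 ± 17.8, and the kinase gene AURKA fell by 0.94 ± 0.07, the cyclin gene CCNB1 by 0.93 ± 0.07 and the securin gene PTTG1 by 0.77 ± 0.04. The proliferation marker MKI67 fell from 304 ± 10.3 to 171 ± 24.6. The phosphatase gene CDC25B rose (0.18 ± 0.06, adjusted p = 0.0345), while PLK1 (-0.25, adjusted p = 0.22) and BUB3 (-0.13, adjusted p = 0.0572) did not pass. Of 42 DNA replication genes, 30 fell and 0 rose, and adjusted over the list alone 37 fell, with a median of -0.32 (camera adjusted p = 1.3e-12). With an estimated correlation this call was lost too (adjusted p = 0.226). The replication factor gene MCM10 fell by 0.88 ± 0.11, the origin licensing gene CDC6 by 0.58 ± 0.07, the thymidylate synthase gene TYMS by 0.48 ± 0.04 and the helicase gene MCM2 by 0.44 ± 0.07. PCNA, the sliding clamp, fell by 0.25 ± 0.07, a call lost with 75th percentile centring (adjusted p = 0.0964). Under quantile normalization and 75th percentile centring 33 mitosis genes fell in each, and 26 and 24 replication genes did.

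Of 23 measured interferon-stimulated genes, 13 fell, 0 rose and 10 did not pass, and adjusted over the list alone 16 fell. The antiviral gene IFIT3 fell from 64.3 ± 2.34 to 40.6 ± 2.72, PARP9 by 0.52 ± 0.09, IFI6 by 0.52 ± 0.09 and the ubiquitin-like modifier ISG15 by 0.38 ± 0.04, from 1219 ± 13.4 to 937 ± 41.5. The median was -0.26 (camera adjusted p = 1.11e-04; adjusted p = 0.484 with an estimated correlation), and 10 members fell after quantile normalization and 9 after 75th percentile centring. Of 25 genes of the integrated stress and unfolded protein response, 13 fell and 1 rose, and adjusted over the list alone 15 fell and 1 rose. The transcription factor gene ATF3 fell from 447 ± 20.8 to 292 ± 26.8, CHAC1, which encodes a glutathione-degrading enzyme, from 508 ± 39.4 to 344 ± 35.4, and the amino acid transporter subunit SLC3A2 by 0.24 ± 0.05. PSAT1, a serine synthesis gene, rose by 0.19 ± 0.05, which the mean of its probe sets did not show (0.0004, adjusted p = 0.997). The median of this list was -0.14 (camera adjusted p = 6.3e-04; adjusted p = 0.381 with an estimated correlation), and the count of falls went from 13 to 10 after quantile normalization and 6 after 75th percentile centring.

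**Figure D3:**
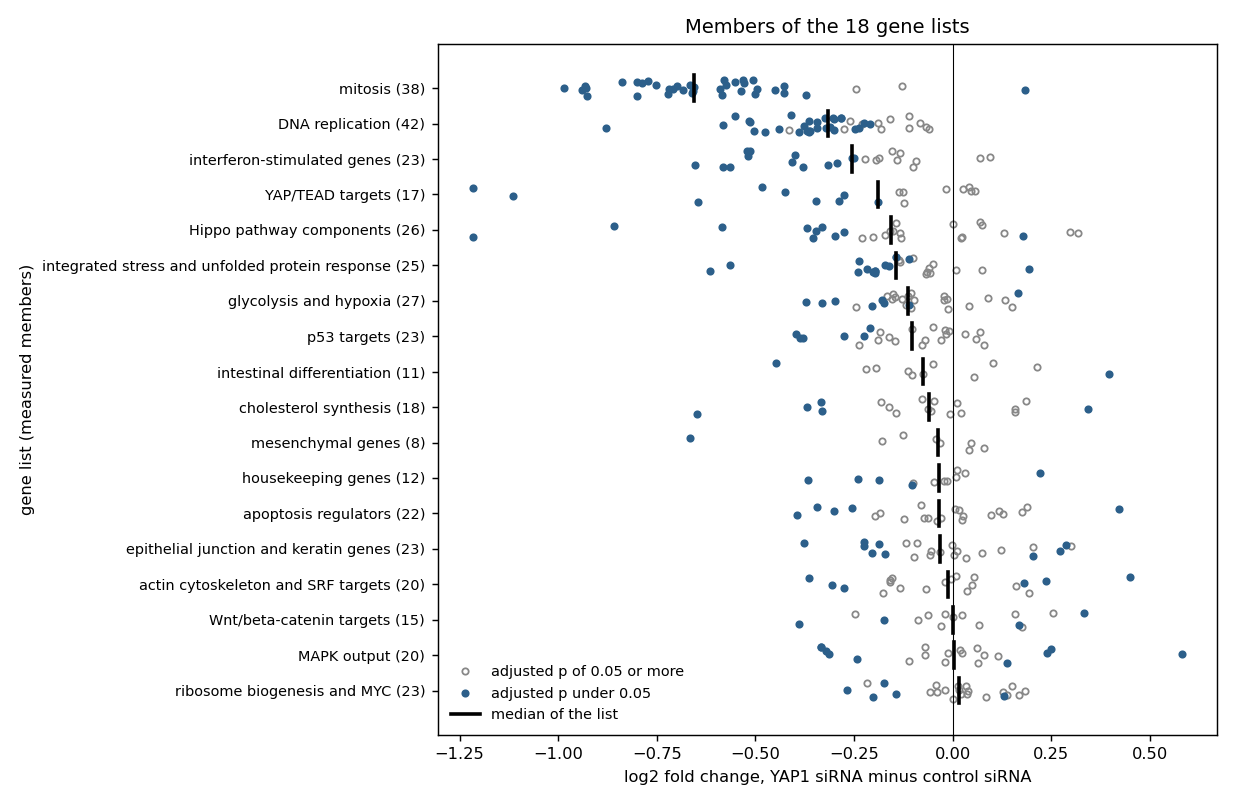
Log2 fold change (YAP1 siRNA minus control siRNA, deposited scaling) of each measured member of the 18 gene lists, with filled points for an adjusted p under 0.05, open points for the rest, and black bars for list medians. Medians are lowest for mitosis (-0.66) and DNA replication (-0.32); other scalings turn the sign of several medians near 0, such as that of cholesterol synthesis.

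The other 12 lists did not pass as lists. Of 23 p53 targets 6 fell and 0 rose (camera adjusted p = 0.151), and adjusted over the list alone 10 fell. TRIAP1 fell by 0.23 ± 0.04 and GADD45A by 0.28 ± 0.07, whereas the cell cycle inhibitor CDKN1A (-0.07, adjusted p = 0.338) and MDM2 (-0.02, adjusted p = 0.916) did not pass. Of 27 glycolysis and hypoxia genes 7 fell and 1 rose (adjusted p = 0.0832), and adjusted over the list alone 12 fell and 1 rose. Quantile normalization gave 6 falls and 3 rises in this list, and 75th percentile centring 3 of each. The glycolytic enzyme genes GPI and HK2 fell by 0.30 ± 0.05 and 0.33 ± 0.06. Of 20 MAPK output genes 4 rose and 5 fell (adjusted p = 0.417), with the same counts over the list alone. The EGFR ligand gene EREG rose from 999 ± 223 to 1473 ± 62.2, and DUSP4 (0.25), DUSP6 (0.24) and IER3 (0.14) rose too, while DUSP5 (-0.33) and ETV5 (-0.31) fell. Of 15 Wnt/beta-catenin targets 2 rose and 2 fell (adjusted p = 0.194), and 3 rose and 2 fell adjusted over the list alone, while under each other scaling 3 rose and 1 fell. CD44 rose by 0.33 ± 0.04 and the Wnt antagonist gene DKK1 fell by 0.39 ± 0.06.

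Of 23 epithelial junction and keratin genes 3 rose and 6 fell (adjusted p = 0.726), and 4 rose and 6 fell adjusted over the list alone. After quantile normalization 4 rose and 4 fell, and after 75th percentile centring 4 rose and 2 fell. With the deposited scaling the rises were the desmosomal genes DSG2 (0.29 ± 0.06) and DSP (0.27 ± 0.05) and the E-cadherin gene CDH1 (0.20 ± 0.04), and the falls included OCLN (-0.38 ± 0.06) and KRT8 (-0.23 ± 0.04). Of 20 actin cytoskeleton and SRF targets 3 rose and 3 fell, with the same counts over the list alone (adjusted p = 0.506), while 4 rose and 2 fell after quantile normalization and 4 rose and 1 fell after 75th percentile centring. TPM4 rose by 0.45 ± 0.07 and VCL fell by 0.31 ± 0.05. Of 8 measured mesenchymal genes, from a list of 18, only THBS1 fell (-0.66 ± 0.14) and 0 rose, adjusted over the list alone too (adjusted p = 0.83). Of 11 measured intestinal differentiation genes, from a list of 26, CA2 fell (-0.45 ± 0.06) and CDX1 rose (0.40 ± 0.10), adjusted over the list alone too (adjusted p = 0.82). Of 18 cholesterol synthesis genes 4 fell, among them INSIG1 (-0.65 ± 0.12), and 1, MVK, rose (0.34 ± 0.09), with the same counts over the list alone (adjusted p = 0.83). Of 22 apoptosis regulators 4 fell, including MCL1 (-0.30 ± 0.05), and 1, CASP8, rose (0.42 ± 0.11), against 5 and 2 over the list alone (adjusted p = 0.772). The balance turned under other scalings, with 4 apoptosis regulators higher and 3 lower after quantile normalization and 5 higher and 3 lower after 75th percentile centring. Of 23 ribosome biogenesis and MYC genes 4 fell and 1 rose, with the same counts over the list alone (adjusted p = 0.198). MYC fell by 0.17 ± 0.04, a call lost under both other scalings (adjusted p = 0.0632 and 0.158), and after quantile normalization 7 members of its list rose and 1 fell. Of 12 housekeeping genes 4 fell and 1, TFRC, rose, with the same counts over the list alone (adjusted p = 0.592), and GAPDH fell by 0.10 ± 0.02, a call lost with 75th percentile centring, where 2 members fell. With the mean of its probe sets TFRC had a log2 fold change of -0.086 (adjusted p = 0.303).

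The median and mean of the actin, epithelial, mesenchymal, intestinal and apoptosis lists were below 0 while camera, which compares them with other genes, placed them higher, and for the ribosome and MAPK lists the median was above 0 and the mean below. In both other scalings the medians of the cholesterol, actin, epithelial, intestinal and apoptosis lists were above 0, and those of the mesenchymal and housekeeping lists were above 0 with 75th percentile centring.

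Markers of other cell types, tested without the filter, were mostly dim and mixed in direction. Of 8 fibroblast markers 0 changed. LYZ fell among 6 leukocyte markers (-0.33 ± 0.10), PECAM1 rose among 7 endothelial markers (0.56 ± 0.15) and TTR rose among 7 hepatocyte markers (0.41 ± 0.11). Among 7 neural markers SNAP25 rose (0.47 ± 0.11) and MAP2 fell (-0.73 ± 0.08). The ratio of 3′ to 5′ signal of ACTB, a sign of RNA integrity, was 5.98 ± 0.64 in control and 6.68 ± 0.50 in YAP1 siRNA arrays, and that of GAPDH was 1.05 ± 0.02 and 1.08 ± 0.03 (exact permutation p = 0.3 for both). The ACTB signal was thus stronger at the 3′ end on every array (ratios of 5.26 to 7.09). With 3 arrays per group the test cannot exclude a difference between groups.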

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

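The tests on the hybridisation and poly-A controls took their final form after the controls' values were seen, and the tests of the other patterns were set before their results were. Probe sets without a gene in the annotation table belonged to no comparison above: of 3437 that passed the intensity filter, 133 were higher and 191 lower with YAP1 siRNA. The lowest of these by log2 fold change was at -1.10 ± 0.07 (363 ± 23.1 to 169 ± 11.5), and the highest was at 1.30 ± 0.26, with control arrays from 55.1 to 138. The hybridisation controls, bacterial and phage transcripts added just before hybridisation, were also outside the comparisons and were higher with YAP1 siRNA by a median log2 of 0.0617.

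More genes were lower than higher, 2082 against 543, and an effect of YAP1 depletion on this balance stays open, as untested. A single scaling factor per array that set the YAP1 siRNA arrays too low would move the hybridisation controls with the median tested gene. These 18 probe sets shifted by 0.0617 ± 0.0241 (SE over arrays, 16 of 18 up), while the median tested gene shifted by -0.0554, which argues against such a factor. Tested genes are those above the intensity filter. Over all non-control probe sets the median intensity was 17.3 to 17.6 on YAP1 siRNA arrays and 16.9 to 17.2 on control arrays. A lower labelling yield stays open: the 24 poly-A controls, which pass through labelling, shifted by -0.1697 ± 0.0774 (21 of 24 down), over 2 SE below 0 as it predicts, but their arrays overlapped between groups (exact permutation p = 0.3). The demand that arrays not overlap was added after this value was seen, and without it the test would have favoured a lower labelling yield. The real grouping called 2625 genes and the highest of the other 9 splits called 0, as 1 of 10 splits, too few for a share under 0.05.

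The mitosis and DNA replication lists were lower. Under the 2 other scalings the highest camera adjusted p of both lists was 2.05e-13. Camera sets a list against other genes, so a shift shared by all genes hardly moves it, and this p cannot decide on scaling. The medians, which such a shift does move, stayed below 0. They were -0.57 for mitosis and -0.24 for replication after quantile normalization, and -0.58 and -0.24 after 75th percentile centring. For these 2 scalings, that argues against array scaling as the whole cause. A fall of all genes of like brightness is argued against too, as the median of the 80 genes was -0.4344 and the central 95% of 10000 random lists matched on intensity ran from -0.116 to -0.0305. These random lists were drawn gene by gene, so their range does not allow for correlation within the lists. Both camera calls were lost with an estimated correlation (adjusted p = 0.226). A smaller share of cycling cells after YAP1 depletion and an effect of this siRNA on other transcripts were not tested and stay open.

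Rises were backed by a second probe set of the same gene less often than falls, in 100 of 267 genes (37.5%) against 542 of 1117 (48.5%), counting a second probe set above the filter with the same direction and an unadjusted p under 0.05 (Fisher's exact p = 0.0013). Array scaling as the cause is argued against by the same comparison after quantile normalization, with 38.0% against 47.6% (Fisher's exact p = 0.000877). Dimmer second probe sets of the higher genes are argued against by genes whose second probe set lay above the 70th percentile, with 45.8% against 59.7% (Fisher's exact p = 0.00139). Rises and falls were not matched on size of change, although a larger change more easily passes the p threshold for backing. Among all changed genes, 20 of 543 rises and 148 of 2082 falls were at least 1.5-fold. After quantile normalization these were 37 of 997 and 87 of 1250. A difference in size, and probe sets that read different transcript ends or bind other transcripts, were not tested and stay open. No biological explanation was tested.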

How the results depend on the processing

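A direction counts as turned here only where the value passed the threshold in either setting. YAP1 kept its call in all 16 alternatives, between -1.60 and -1.31. Counts of genes depended on the processing, and the causes were not tested. Quantile normalization gave 997 higher and 1250 lower genes, 75th percentile centring 1146 and 1164, eBayes without the trend 343 higher, and the mean of probe sets 1700 changed with 311 higher. Testing every probe set gave 4097 changed, 922 higher and 3175 lower, over more items. Leaving out 1 array gave 1475 to 3126 changed, 234 to 896 higher and 1196 to 2230 lower genes. The total moved by over 1.5 times without control array 2 (1604), YAP1 siRNA array 2 (1493) or YAP1 siRNA array 3 (1475), and so did the lower genes (1307, 1259 and 1196). The higher genes did so without control array 1 (327), 2 (297) or 3 (896), or YAP1 siRNA array 2 (234) or 3 (279). With an estimated correlation all 5 list calls were lost, with adjusted p-values of 0.381 for YAP/TEAD targets, 0.226 for DNA replication, 0.226 for mitosis, 0.484 for interferon-stimulated genes and 0.381 for the stress response. Fry, which does not set a list against other genes, kept all 5 lower. Its adjusted p-values were 0.00436, 0.00391, 0.00311, 0.0222 and 0.00484 in the same order. The Hippo list passed with 75th percentile centring (0.0206), no filter (0.0023), without _x_at probe sets (0.0255) and with fry (0.00484), and ranged from 0.0232 to 0.138 when 1 array was left out, passing without control array 2 (0.0232), YAP1 siRNA array 2 (0.0388) or YAP1 siRNA array 3 (0.0446). The p53 list passed with no filter (0.00764) and fry (0.0071), the glycolysis and hypoxia list with no filter (0.0025), fry (0.0194) and without control array 2 (0.0493, range 0.0493 to 0.205), and the housekeeping list with fry (0.0283). The replicate numbers did not pair the arrays, as deviations of same-numbered arrays from their group means correlated at -0.02, -0.03 and -0.02 across genes. With the number as a block 2322 genes changed, 480 higher and 1842 lower, and no list changed its call. For the 92 genes named by the fixed parts of the rule besides YAP1, 1375 of 1445 results kept direction and call, 68 lost the call, 1 gained it (TEAD1) and 1 reversed: TFRC, from 0.22 to -0.086 with the mean of probe sets (adjusted p = 0.303). For the 16 members picked later, 230 of 255 results were kept and 25 lost the call. IDI1 fell by 0.37 but had -0.02 without _x_at probe sets. Signal over background limits genes near the filter intensity of 17.3, such as MMP1, PRDM1 and CCN2.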

Other observations

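The gene groups in the next paragraph, and the test of each, were chosen after the data were seen, while the brightness tests of the last paragraph were set before their results were. Adjusted p-values of groups cover 18 Fisher's exact tests, of falls and rises in 9 groups. These tests treat genes as independent, so a shift shared by the genes of a group makes their p-values too small.

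Of 7 mitochondrially encoded protein genes 6 rose and 0 fell (Fisher's exact adjusted p = 6.91e-07 for rises), with 3 rises after quantile normalization and 7 after 75th percentile centring. Set against the falls among changed genes, these rises gave an unadjusted Fisher's exact p of 7.66e-05 with the deposited scaling, 0.0872 after quantile normalization and 0.00733 after 75th percentile centring. The log2 fold change was 0.11 ± 0.02 for COX1, 0.10 ± 0.02 for ND4 and 0.64 ± 0.17 for the dimmer ND6. ND4 had the highest intensity of any probe set on each YAP1 siRNA array (13418 ± 53.7), so the size of its change is uncertain at the top of the range. COX1 (12223 ± 98.9), COX2 (11812 ± 72.4) and ATP6 (11093 ± 192) were nearly as bright on those arrays, so the same limit holds for them. Of 11 tubulin genes 7 fell (adjusted p = 0.00242), and the count was 7 under each other scaling too. With the deposited scaling these included TUBB (-0.30 ± 0.04) and TUBA1B (-0.28 ± 0.03). TUBB, TUBA1B, TUBA1C, TUBB3 and TUBB4B, all among the falls, were read by _x_at probe sets, which may bind several transcripts. Their falls may therefore not be separate, although the count and its adjusted p treat them so. Of 17 centromere protein genes 11 fell (adjusted p = 8.81e-05), such as CENPE (-0.75), CENPU (-0.61) and CENPW (-0.45), with 7 after quantile normalization and 8 after 75th percentile centring. Of 36 kinesin genes 13 fell and KIF9 rose by 0.41 (adjusted p = 0.0171 for falls), with 11 falls under each other scaling. KIF20A fell by 0.93 and KIF18B by 0.67. The mitosis and replication lists already held 3 of these centromere protein genes and 5 of the kinesins. Zinc finger (ZNF) genes fell less often than other genes, with 23 falls and 13 rises among 291 (adjusted p = 0.000217 for falls), and had 14 falls and 34 rises after quantile normalization. The other groups did not pass for falls or rises: 4 of 49 cytosolic ribosomal protein genes fell and 4 rose, 14 of 75 mitochondrial ribosomal protein genes fell and 1 rose, and 7 of 22 nucleoporin and 9 of 32 proteasome subunit genes fell with 0 rises. After quantile normalization 2 cytosolic ribosomal protein genes fell and 6 rose, and 5 mitochondrial ones fell and 4 rose. In that scaling 3 nucleoporin and 4 proteasome subunit genes fell, again with 0 rises. Long non-coding RNAs made up 5.11% of tested genes, 9.39% of risers (51 genes) and 1.97% of fallers (41 genes; Fisher's exact p = 8.29e-14 for risers against fallers). The shares of risers and fallers were 5.22% and 2.32% after quantile normalization, where that of risers was close to the share of tested genes, and 6.11% and 1.55% after 75th percentile centring.

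Set against 10000 random lists matched on mean intensity, the median of the 17 YAP/TEAD targets was -0.1879, where the central 95% ran from -0.1575 to 0.0294 and 55 lists were as low. The median of the 23 interferon-stimulated genes was -0.2558, where the central 95% ran from -0.1539 to 0.012 and 0 lists were as low. The random lists were drawn gene by gene, so these ranges do not allow for correlation within a list. The estimated correlation was 0.12 for YAP/TEAD targets and 0.43 for interferon-stimulated genes. With it, camera's adjusted p-values were 0.381 and 0.484.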
